A study of Scenedesmus vacuolatus with 30 samples.

How the data were processed

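Transcript levels were measured in the unicellular green alga Scenedesmus vacuolatus after 14 h in culture with triclosan, an antimicrobial compound, or with the solvent alone. Per the labels' protocols, the cultures grew in an inorganic medium at 28 °C, the exposed cultures received 1 of 5 concentrations, and the solvent, DMSO, stood at 0.1%. For each replicate, per the same protocols, 2 suspensions of 80 mL were pelleted, total RNA was purified, and 50 ng was labelled with Cy3 and put on a one-colour Agilent array. The series holds 30 arrays in 6 groups of 5, which are the solvent control and, from the highest down, 6.63, 3.77, 2.15, 1.22 and 0.69 µg/L. The groups were taken from the source label of each sample. For the highest concentration that label and the protocol give 6.63 µg/L while a second label gives 6.31 µg/L, and 6.63 µg/L was used throughout. The labels number the replicates without saying whether each was a separate culture, so p-values measure the spread between these samples.

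Each array was scanned and quantified with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes. The deposited scanner tables give, per spot, a processed signal on a linear intensity scale, from which the software had subtracted background and spatial trends, with a surrogate value for spots near the background, per the file headers, together with the raw mean and local background intensities. Each array carried 62976 spots, of which 61537 were not controls. These held 42974 different probes of 60 nt for 21495 contigs (assembled transcript sequences), and 18563 of the probes were printed 2 times. In 21479 contigs there were 2 probes, which in 75.6% of these contigs overlapped by at least 20 nt, with a median offset of 1 nt, so the pair is a repeat measurement of nearly the same stretch. The tables name a contig for each probe and pair it with no gene name or description, and no genome was given. The 20 gene lists fixed beforehand could therefore not be applied, and contigs are identified by their contig name, probe number and probe sequence, with no genome position.

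The submitters also deposited a table of 61535 rows of log2 values for the same 30 arrays, with column medians from 4.62 to 4.94. Its columns were matched to the samples by name, and 0 columns were left unused. Cyclic loess between arrays of the log2 processed signals gave values that correlated with these columns at r from 0.999 to 1.000 across probes and differed from them by a median of -0.0002 to 0.0498 on the log2 scale. For this comparison 2 columns at 1.22 µg/L were exchanged, as described in the closing part. The scale of the table is thus log2, its direction is that of the signal, and how its centre was set is not given in the sources used here.

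From the scanner tables, log2 of the processed signal was taken, spots marked as outliers by the scanner software were removed, and spots of one probe were averaged. The 75th percentile of each array was then subtracted, and these differences are called scaled signals below. A probe was tested if it lay well above background, by the scanner's own mark, on all 5 arrays of at least 1 group. This left 19950 probes of 11009 contigs, both probes of 8941 contigs among them, and 23024 probes were not tested. Among the tested probes 158 single values were missing. One linear model with 6 group means was fitted to all 30 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided), which leaves 24 residual degrees of freedom. Probes with a Benjamini-Hochberg adjusted p under 0.05 are called. Errors of log2 fold changes are the standard errors of this model, after moderation of the variance. The trend was tested with a limma F test of the linear and quadratic terms of the concentration rank. Tables were read with Python 3.11.15 and pandas 2.3.3.

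Where a probe was not well above background on any array of a group, the fold is given as a bound. It sets the mean of the brighter group against a dim group in which each array takes the higher of its own value and the lowest scaled signal of any probe marked well above background on that array. Folds of other dim probes are those of the model.

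For probes past the trend test, linear, exponential, Hill and Gauss curves over concentration were fitted by least squares on a grid and chosen by the corrected Akaike criterion. The benchmark concentration is the lowest concentration at which the fitted curve lies 1 residual SD from its value at 0. Intervals for single probes are the 95% range of 200 resamples of the arrays within groups. The steps were tested on simulated data. Normal noise was drawn for 19799 probes around their real means with their real residual SDs, and known changes that grew with concentration were added. The noise was independent between probes and between arrays, so it lacked the correlations of the real arrays. The recoveries and false calls are those of such noise and do not give the rates in these data. At the highest concentration the contrast recovered 5 of 50 probes changed 1.5-fold, 19 of 50 changed 2-fold, 41 of 50 changed 3-fold and 45 of 50 changed 5-fold, with 6 false calls. Benchmark concentrations of simulated Hill curves had a median ratio of 0.828 to the true value, and 67.3% of 300 lay within 1.5-fold. These curves all had the same slope and the same height over the noise, and no other form was simulated. In the data a Hill curve was chosen for only 76 rising and 127 falling probes, so the accuracy for most probes was not tested. Of 1000 flat curves, 800 were called constant.

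The arrays lay on 5 slides, as the barcodes in the file headers show. Each slide held 1 array of every group, and the replicate number was the number of the slide. Deviations from the group means correlated at a mean of 0.31 between arrays of one slide (75 pairs) and of -0.08 between slides (300 pairs), and 23 of 30 arrays correlated best with their own slide. This was uneven: mean r was 0.56 on slide 2 but 0.12 and 0.14 on slides 1 and 3. Of the 75 pairs 53 had r above 0.1, and r between control and 6.63 µg/L arrays of one slide ranged from -0.52 to 0.69. The replicate number was thus taken to pair the arrays, but only in alternative fits. The main model has no slide term, so its counts, errors and p-values leave the pairing out. Counts with the slide as a fixed block are given where they differ by over 1.5-fold. Below that limit, the block gave 7181 calls at 6.63 µg/L and 11459 for the trend. Every group occupied the same array position on all 5 slides, so position and concentration cannot be told apart.

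The alternatives tried were quantile and cyclic loess normalization, normexp background correction (offset 50) with the 75th percentile or with quantile normalization, the array median as scale, no filter and a filter on all 30 arrays, and slide as a fixed or random block. Others were the submitters' values, a robust variance model, each replicate or array left out, other codings of concentration, only the 10 arrays compared, and other curves and thresholds. These, the design and the rule for named probes were fixed before the data were examined. The rule, where probes carry no gene names, takes the 2 highest and 2 lowest log2 fold changes at 6.63 µg/L and the 2 rising and 2 falling probes with the smallest trend p. Each must be called, lie well above background on all 5 arrays of the control or of the 6.63 µg/L group, and have all 5 exposed arrays on one side of the control mean, with 1 probe per contig, that with the smallest p. It named 7 contigs.

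Between 40.2% and 62.4% of the spots of an array lay well above background, no spot was marked saturated, and the 75th percentile of the processed signal ranged from 91 to 514. The scanner software marked 1 to 198 spots per array as outliers. The number of arrays, 5 per group, limits the precision. The median residual SD of a tested probe was 0.49 on the log2 scale.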

Results

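Transcript abundance in Scenedesmus vacuolatus was profiled on 30 one-colour arrays to follow its response to triclosan over 5 concentrations and a solvent control, with 5 arrays per group. The series title ties the set to a method for dose-response modelling of omics data. The share of spots well above background averaged 46.3% ± 5.4 (SD, n = 5) in the control, 54.6% ± 3.9 (SD, n = 5) at 1.22 µg/L and 48.1% ± 5.2 (SD, n = 5) at 6.63 µg/L. In the control 14908 probes were well above background on all 5 arrays. Changes are given for the 19950 probes that passed the detection filter, and contigs are named without a gene because the arrays' tables give none.

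The number of probes called against the control rose with concentration, but the direct test from 2.15 to 3.77 µg/L called only 15 probes. That from 3.77 to 6.63 µg/L called 6132. No probe was called at 0.69 µg/L, 132 were called at 1.22 µg/L, 159 at 2.15 µg/L, 1568 at 3.77 µg/L and 5200 at 6.63 µg/L (limma, adjusted p under 0.05).

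**Figure D1:**
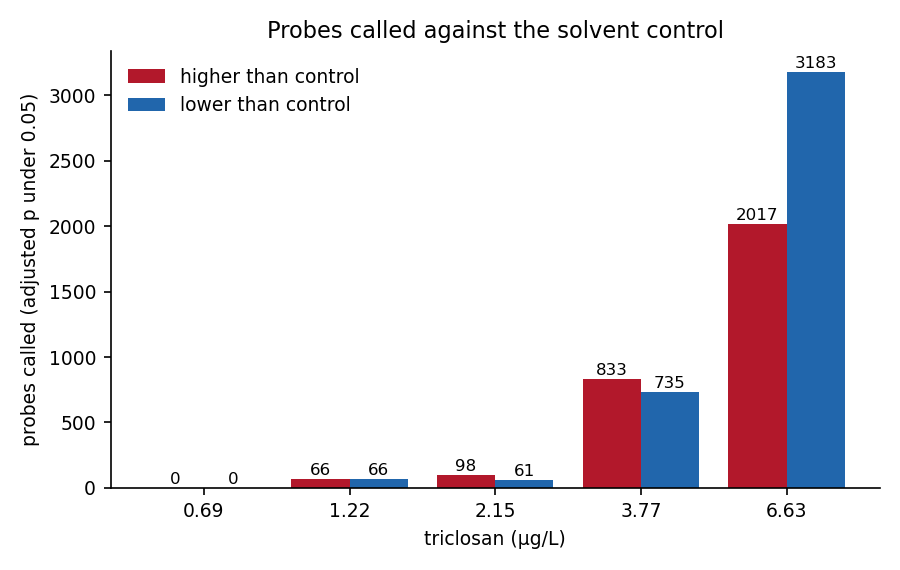
Number of probes called higher (red) and lower (blue) than the solvent control at each triclosan concentration (x axis, µg/L), with limma at an adjusted p under 0.05. Counts rose from 0 at 0.69 µg/L to 2017 higher and 3183 lower at 6.63 µg/L, a split between directions that moved to 2847 and 2887 after cyclic loess.

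At 6.63 µg/L against control, contig15173 and contig08443 were the 2 risers named by the rule and contig00289 and contig21321 the 2 that fell. The scaled signal of contig15173 went from -3.39 ± 0.85 (SD, n = 5) in the control to 5.75 ± 0.81 (SD, n = 5), a log2 fold change of 9.14 ± 0.56 (SE) (limma adjusted p = 1.63e-12). Only 1 of the 5 control arrays held it well above background, so the size depends on how background is treated, and normexp background gave 7.12. Contig08443 was not well above background on any control array and rose to a scaled signal of 4.09 ± 1.86 (SD, n = 5) at 6.63 µg/L (limma adjusted p = 7.59e-11). On the processed signals this is at least 133-fold, a bound that depends on how background is treated, since the fitted log2 fold change with normexp background was 5.74. Contig00289 fell by 4.70 ± 0.63 (SE) on the log2 scale, a 26.0-fold drop (limma adjusted p = 2.08e-06), and at 6.63 µg/L 4 of 5 arrays still held it well above background. Contig21321 fell by 4.55 ± 0.61 (SE) on the log2 scale, or 23.4-fold (limma adjusted p = 2.49e-06). The log2 fold change of contig00289 was -3.79 without slide 5 and -5.27 without slide 4, and that of contig21321 was -3.715 and -5.10.

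The probe for contig15173 (CUST_29810_PI429914804) has the sequence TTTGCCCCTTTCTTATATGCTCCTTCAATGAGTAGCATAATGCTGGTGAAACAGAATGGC, and the second probe of that contig changed by 9.0 on the log2 scale. The probe for contig08443 (CUST_16350_PI429914804) reads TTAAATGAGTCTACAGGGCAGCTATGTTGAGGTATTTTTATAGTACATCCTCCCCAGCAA. The probes for contig00289 (CUST_371_PI429914804, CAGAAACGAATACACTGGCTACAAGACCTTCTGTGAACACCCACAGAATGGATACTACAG) and contig21321 (CUST_42014_PI429914804, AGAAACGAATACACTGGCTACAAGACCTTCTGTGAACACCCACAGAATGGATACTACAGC) are the same stretch shifted by 1 nt, so their falls are not independent. On all 5 slides the array at 6.63 µg/L lay above the control array of that slide for contig15173, by 7.85 to 10.91 on the log2 scale. The size of these differences depends on how background is treated, since only 1 of the control arrays held the probe well above background. For contig00289 these differences ran from -8.34 to -2.41.

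Across the array 2017 probes were higher and 3183 lower at 6.63 µg/L. Of these, 1342 rose and 1902 fell at least 2-fold, and 320 rose and 279 fell at least 4-fold. Both probes were called higher in 830 of the 8941 contigs with a tested pair and both lower in 1207, while 850 had 1 probe called and 0 had probes called in opposite directions. The log2 fold changes of the paired probes correlated at r = 0.94 across contigs, which are not independent replicates.

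The median log2 fold change of all tested probes at 6.63 µg/L was -0.16, against -0.02 after cyclic loess and -0.03 with the array median as scale. Relative to that median, contig15173 changed by 9.30 and contig00289 by -4.54. The share of called probes that were higher, 38.8%, moved to 49.7% (2847 higher, 2887 lower) after cyclic loess, to 49.6% (2833 and 2874) with the submitters' values and to 51.0% (1549 and 1490) with the array median. The submitters' values nearly equal the cyclic loess values, as given above, so here and below they are not a separate alternative to cyclic loess. Leaving out slide 3 lowered the count of calls from 5200 to 3375, and fitting only the 10 arrays of these groups gave 2570.

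At 3.77 µg/L against control, 833 probes were higher and 735 lower, a balance that turned with the scaling. Quantile normalization gave 937 higher and 1021 lower, cyclic loess 989 and 1104, and the submitters' values 979 and 1088. Contig15173 changed by 4.85 ± 0.56 (SE) on the log2 scale (limma adjusted p = 2.03e-06), a size that depends on how background is treated, as described above. Contig11436 rose 5.13-fold, with a log2 fold change of 2.36 ± 0.38 (SE) (limma adjusted p = 3.63e-04). Contig08443, not well above background on any control array, was so on 4 of 5 arrays at 3.77 µg/L, where its scaled signal was -1.96 ± 1.01 (SD, n = 5) (limma adjusted p = 0.00974). Contig00289 lay at -1.24 ± 0.63 (SE) and contig02939 at -0.17 ± 0.36 (SE) on the log2 scale, neither of which passed the test (limma adjusted p = 0.211 and 0.788).

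Both probes were called higher in 311 contigs and both lower in 242. At least a 2-fold change was seen for 563 of the higher and 491 of the lower probes. With slide as a block 3402 probes were called (1752 higher, 1650 lower), and normexp background gave 1026. The count of 1568 fell to 657 without control array 1, to 801 without control array 5, to 497 and 707 without array 1 or 3 at 3.77 µg/L, and to 362 when control arrays 1 and 5 were both left out. Without slide 1, 3 or 5 it was 202 (155 higher, 47 lower), 473 or 906, and with only the 10 arrays compared 556. The array median as scale gave 389.

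At the lower concentrations few probes were called, and none of the 7 named contigs was among them. At 2.15 µg/L 98 probes were higher and 61 lower, with both probes higher in 32 contigs and both lower in 21. The scaled signal of contig15173 was -2.76 ± 0.90 (SD, n = 5) at 2.15 µg/L, against -3.39 ± 0.85 (SD, n = 5) in the control (limma adjusted p = 0.618). Contig11436 lay at -1.76 ± 0.33 (SD, n = 5) against -2.49 ± 0.32 (SD, n = 5) (limma adjusted p = 0.392). With slide as a block 723 probes were called at 2.15 µg/L, 497 higher and 226 lower. With the array median as scale 8 were higher and 21 lower. Leaving out control array 1 or 5 gave 49 or 59 calls, both together 5, and leaving out array 1, 2, 3, 4 or 5 at 2.15 µg/L gave 17, 87, 17, 79 or 369. Without slide 1, 2, 3, 4 or 5 there were 0, 39, 0, 3 or 260 calls, of which 0, 9, 0, 2 or 169 were higher.

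At 1.22 µg/L 66 probes were higher and 66 lower, with both probes higher in 21 contigs and both lower in 26. Of these calls 58 rose and 64 fell at least 2-fold. Contig15173 was not well above background on any array at 1.22 µg/L, and contig02939 lay 0.37 ± 0.36 (SE) above the control on the log2 scale (limma adjusted p = 0.853). The slide block gave 529 calls (320 higher, 209 lower), and the array median as scale gave 2 higher and 25 lower. Without control array 1, 3, 4 or 5 the count was 58, 76, 81 or 66, without both arrays 1 and 5 it was 11, and without array 1, 2, 3 or 4 at 1.22 µg/L it was 33, 52, 34 or 49. Without slide 1, 2, 3, 4 or 5 there were 1, 62, 13, 12 or 202 calls, of which only 0, 6, 0, 0 or 119 were higher.

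At 0.69 µg/L no change was called by limma, and 385 probes had an unadjusted p under 0.05 where 998 would be reached by chance. The scaled signal of contig15173 was -2.89 ± 0.64 (SD, n = 5) and that of contig21321 was 4.32 ± 0.90 (SD, n = 5), against 4.65 ± 1.24 (SD, n = 5) in the control (limma adjusted p = 0.967 for both). The slide block, the other normalizations and filters, and each array or slide left out also gave 0 calls.

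The steps between neighbouring concentrations were tested directly. From 2.15 to 3.77 µg/L 15 probes rose and none fell, and all 15 rose at least 2-fold. Among them contig15173 rose by 4.22 on the log2 scale (limma adjusted p = 2.33e-04) and contig08443, which was not well above background on any array at 2.15 µg/L, was called higher (limma adjusted p = 0.0369). Of the unadjusted p-values of this step 830 were under 0.05, fewer than the 998 expected by chance, and the slide block gave 72 calls, 55 higher and 17 lower. Without slide 1, 3 or 4 the step gave 2, 2 or 3 calls.

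From 3.77 to 6.63 µg/L 2184 probes rose and 3948 fell. Contig02939 and contig02141, which were not called at 3.77 µg/L, dropped by 3.48 and by 2.35 on the log2 scale in this step (limma adjusted p = 7.53e-08 and 1.04e-07). Contig08443 rose by a further 6.05 and contig15173 by a further 4.28 (limma adjusted p = 1.24e-07 and 2.39e-06). Both probes rose in 888 contigs and both fell in 1524, while 4 had probes called in opposite directions. The median of all tested probes moved by -0.20 in this step, and the 35.6% of calls that rose became 52.7% after cyclic loess, 52.6% with the submitters' values, 47.6% with normexp and quantile normalization and 49.6% with the array median. Leaving out slide 1 or 3 lowered the count of 6132 to 3367 or 2925.

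Over all 6 groups the trend test called 8880 probes, 3518 with a rising and 5362 with a falling linear term. The rising probes with the smallest p were those of contig15173 and of contig11436 (CUST_22336_PI429914804, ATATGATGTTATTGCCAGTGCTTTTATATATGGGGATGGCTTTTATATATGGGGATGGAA), with limma adjusted p = 1.43e-14 and 1.51e-14. Contig11436 rose from -2.49 ± 0.32 (SD, n = 5) in the control, where 3 of 5 arrays held it well above background, to 4.40 ± 1.21 (SD, n = 5) at 6.63 µg/L, a log2 fold change of 6.89, or of 5.53 with normexp background. The falling probes with the smallest p were those of contig02141 (CUST_3786_PI429914804, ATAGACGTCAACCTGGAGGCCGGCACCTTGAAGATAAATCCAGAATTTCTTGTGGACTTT) and contig02939 (CUST_5342_PI429914804, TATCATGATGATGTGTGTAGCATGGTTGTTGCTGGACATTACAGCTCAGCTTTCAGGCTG), with limma adjusted p = 8.36e-11 and 2.65e-10. Contig02141 went from 1.23 ± 0.28 (SD, n = 5) in the control to 1.70 ± 0.38 (SD, n = 5) at 2.15 µg/L and -1.36 ± 0.52 (SD, n = 5) at 6.63 µg/L, 6.01-fold below the control. Its second probe changed by -1.72 on the log2 scale, and normexp background gave -1.81 in place of -2.59. Contig02939 went from 3.29 ± 0.31 (SD, n = 5) in the control to -0.36 ± 0.95 (SD, n = 5) at 6.63 µg/L, 12.5-fold lower.

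**Figure D2:**
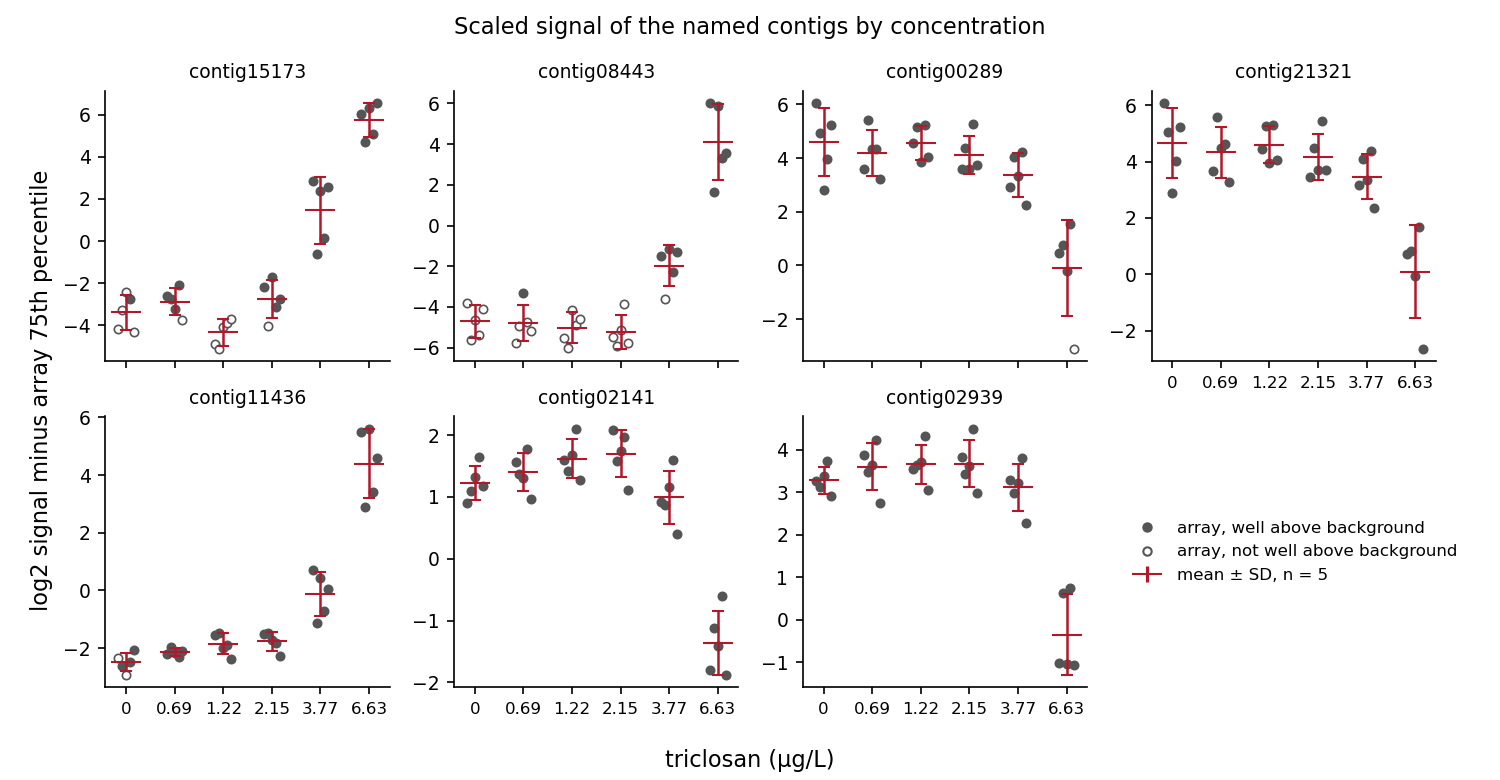
Scaled signal (y axis, log2 processed signal minus the array's 75th percentile) of the 7 named contigs against triclosan concentration (x axis, µg/L, evenly spaced groups). Each point is an array, open where the probe was not well above background, and red bars are the mean ± SD (n = 5). Contig15173 rises at 3.77 and again at 6.63 µg/L, while contig02939 stays near the control up to 3.77 µg/L and is 12.5-fold lower at 6.63 µg/L.

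Both probes were called with a rising linear term in 1429 contigs and with a falling one in 2119, and 91 had called probes with opposite signs. That sign need not pass a test by itself: the linear term called both probes rising in 861 contigs and both falling in 1195. The linear term alone called 5318 probes, 2092 rising and 3226 falling. The rising share of the trend calls, 39.6%, became 50.4% after cyclic loess and with the submitters' values and 49.1% with the array median, where that of the linear term became 50.6%. Without the 6.63 µg/L group the trend test called 2196 probes, 1242 rising and 954 falling, and without slide 1 it called 5581.

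Curves were fitted to the 8815 trend probes with no missing value to ask at which concentration each first left the control level. By shape of the chosen curve 2372 probes rose, 3448 fell, 2001 were fitted best by a bell and 982 by a U, and 12 were best described as constant. The median benchmark concentration was 2.75 µg/L, with quartiles of 1.26 and 5.30 µg/L. Falling probes had a median of 4.57 µg/L and rising probes of 3.61 µg/L. Probes with bell-shaped and U-shaped fitted curves had medians of 1.2 and 1.3 µg/L. These medians are crossings of fitted curves and not called changes. At 1.22 µg/L only 132 probes were called against the control and 0 against the 0.69 µg/L arrays. A bell does not mean that the signal turned back, since the peak can lie near the highest concentration, as for contig08443. Benchmark concentrations of 3.77 µg/L or more were found for 2070 of the 3448 falling and 1122 of the 2372 rising probes, a range with no tested concentration below 6.63 µg/L, where the value rests on the form of the curve.

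Among the named contigs, contig11436 had a benchmark concentration of 1.62 µg/L (95% resampling interval 0.93 to 2.20) and contig15173 of 2.57 µg/L (0.43 to 2.75). That of contig08443 was 3.34 µg/L (0.49 to 3.66), on a bell-shaped curve. Contig00289 and contig21321 gave 3.60 µg/L (1.29 to 4.95) and 3.62 µg/L (1.23 to 4.94). For contig02939 the value was 4.24 µg/L (0.52 to 6.05), and for contig02141, on a bell-shaped curve, 0.58 µg/L (0.33 to 5.21). The overall median became 5.08 µg/L when only linear, exponential and Hill curves were allowed and 5.52 µg/L when the threshold was 2 residual SDs, and 1.75 µg/L without slide 4.

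**Figure D3:**
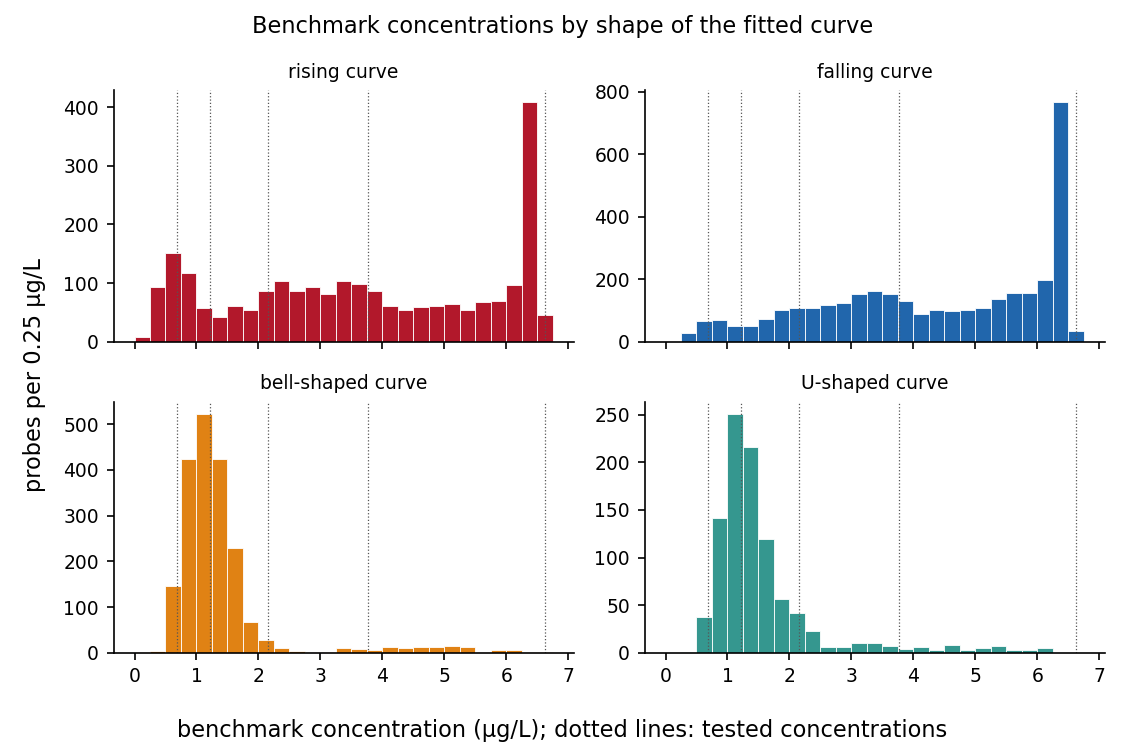
Number of probes (y axis, per 0.25 µg/L) by benchmark concentration (x axis, µg/L) for rising, falling, bell-shaped and U-shaped fitted curves, with dotted lines at the tested concentrations. Bell-shaped and U-shaped curves gather near their medians of 1.2 and 1.3 µg/L, and rising and falling curves spread up to 6.63 µg/L. The bin from 6.25 to 6.5 µg/L holds 408 rising and 766 falling probes, more than any other bin of these shapes.

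The response at 6.63 µg/L was compared with that at 3.77 µg/L probe by probe. Both concentrations called 727 probes in the same direction, 409 higher and 318 lower, and 38 in opposite directions. Of the 833 probes higher at 3.77 µg/L, 86 rose further by the direct test of the step to 6.63 µg/L and 297 turned back, and their median log2 fold change went from 1.17 to 0.73. Of the 735 lower probes, 37 fell further and 216 turned back, and the median went from -1.17 to -0.70. These probes were selected on the same 3.77 µg/L arrays that the step subtracts, which favours turning back over moving further. Probes called higher at 6.63 µg/L had a median log2 fold change of 0.39 at 3.77 µg/L and 1.23 at 6.63 µg/L, and those called lower had -0.16 and -1.10.

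Independent lists of these lengths would share 201.5 probes. Both comparisons use the same control arrays: with the controls split between the comparisons the shared calls had a median of 173.5 (67 to 579 over 20 splits). The lists then held a median of 374 calls at 3.77 µg/L and 3768 at 6.63 µg/L. Some splits gave longer lists than the fit with all control arrays, of up to 5785 and 6176 calls. Independent lists of the lengths in each split would share a median of 23.8 probes (8.8 to 892.2). The shared calls exceeded the number for independent lists in 18 of the 20 splits. They fell below it where the 3.77 µg/L list was longest, with 579 against 892.2 and 456 against 553.5. Neither number for independent lists takes into account that the arrays of both concentrations lie on the same 5 slides. With slide as a block 1589 were shared, without slides 1, 3 or 5 the numbers were 150, 304 or 443, and without control arrays 1 and 5 the number was 275. With the array median as scale 217 were shared, and with no filter 449.

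Whole profiles of log2 fold change were compared between concentrations. Across 19799 probes, which are not independent replicates, r was 0.86 between 2.15 and 3.77 µg/L, 0.31 between 3.77 and 6.63 µg/L, and 0.03 between 0.69 and 6.63 µg/L. Simulated unchanged groups with shared controls, which did not keep the slides, gave a median r of 0.53 and a 95th percentile of 0.90. None of these r thus lies above what the shared controls alone can give. With split controls the median r was 0.58 (0.12 to 0.71 over 20 splits) between 2.15 and 3.77 µg/L, 0.46 (-0.14 to 0.72) between 1.22 and 2.15 µg/L and 0.22 (-0.37 to 0.48) between 0.69 and 1.22 µg/L. It was 0.22 (-0.23 to 0.43) between 3.77 and 6.63 µg/L and -0.10 (-0.47 to 0.13) between 0.69 and 6.63 µg/L. The covariance exceeded the simulated mean of 0.075, whose spread over simulations is not given, by 0.204 between 2.15 and 3.77 µg/L. It did so by 0.101 between 3.77 and 6.63 µg/L and by 0.110 between 1.22 and 2.15 µg/L. The difference was 0.026 between 0.69 and 1.22 µg/L and -0.067 between 0.69 and 6.63 µg/L.

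Arrays also differed within groups. The first component of the deviations from the group means held 37.0% of the within-group variance. On it control arrays 1 and 5 had scores of 94.4 and 48.4 and the other 3 control arrays scores from -60.8 to -39.8. At 6.63 µg/L arrays 1 and 3 had scores of 74.7 and 73.2, array 4 of 8.4, and arrays 2 and 5 of -84.3 and -72.0. Other groups also held high scores, with 64.1 for array 4 at 2.15 µg/L and 57.3 for array 4 at 3.77 µg/L.

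**Figure D4:**
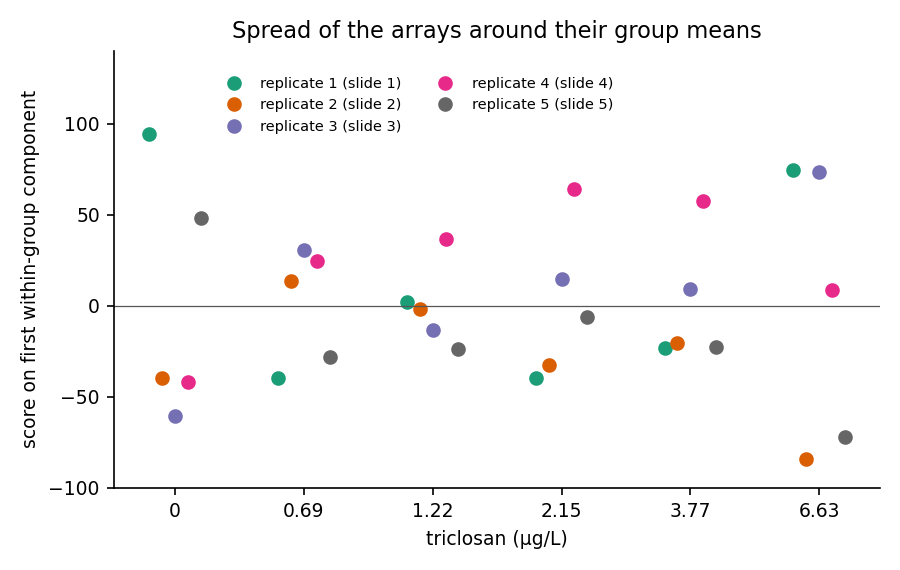
Score of each array on the first component of the deviations from the group means (y axis, no unit) by triclosan concentration (x axis, µg/L), coloured by replicate number, which is the slide. Control arrays 1 and 5 and arrays 1 and 3 at 6.63 µg/L lie highest in their groups, with scores from 48.4 to 94.4. Array 4 has scores of 64.1 at 2.15 µg/L and 57.3 at 3.77 µg/L.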

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

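The test of the slide, that of the 215 shared calls and the fits without control arrays 1 and 5 were chosen after the results had been seen.

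On 1 array the negative controls, which enter no comparison, held a signal: at 3.77 µg/L, replicate 1, one of the 308 negative-control spots had a raw intensity of 315714, against at most 942 on the control arrays and 46 to 82 for the same spot on the other 29 arrays. Of its 8 neighbouring spots 3 were also above 100000 on this array, the spot carried the scanner's outlier mark, and the median of the negative controls there was 60.6. No sample lay far from the others of its group in the 60 sets of 5 values examined for the named contigs and the array measures, where chance would mark about 3.

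Regrouping the arrays asked whether chance could give as many calls, over the 19799 probes with no missing value. Of 100 splits of the 10 arrays into groups of 5, the real one included, only the real split reached 134 calls at 1.22 µg/L (next highest 0) and 1562 at 3.77 µg/L (next highest 663). At 2.15 µg/L 2 splits reached the real 158, the other with 1512 calls, at 6.63 µg/L 4 reached 5174, the highest other with 8129, and for the step to 6.63 µg/L 2 reached 6091, the other with 6571. For the step from 2.15 to 3.77 µg/L 2 reached 16, the other with 73. Each of these real counts was thus reached by a share of splits under 0.05, with no correction for the number of results. Since these splits ignore the slides, they do not exclude chance for arrays that are paired by slide. For 0.69 µg/L the splits decide nothing, since any split reaches the real 0 calls, as all 100 did (highest other 5). Over 100 assignments of the 30 arrays to 6 groups, which also ignore the slides, 1, the real one, reached 8816 trend calls (next highest 0) and 5289 linear trend calls (next highest 1). For the 722 calls shared by 3.77 and 6.63 µg/L, which also only the real one reached (next highest 0), this does not test sharing apart from the number of calls at each concentration. Of the splits that part all 5 slides, as the real one does, none of the 11 drawn at 6.63 µg/L and none of the 12 drawn for the step to it reached the real count, with at most 969 and 3012 calls, but these splits are too few for a share under 0.05.

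The split with 8129 calls set control arrays 1 and 5 and arrays 1, 3 and 4 at 6.63 µg/L against the rest, and that with 1512 set control arrays 1 and 5 and arrays 3, 4 and 5 at 2.15 µg/L against the rest, so both point to the structure seen in the first within-group component. The values below argue against the slide, intensity-dependent bias and GC content as the whole source of that component. The slide explained 19.0% of the variance of the scores (permutation p = 0.361, 10000 permutations, whose 95th percentile was 35.8%). After cyclic loess, which removes intensity-dependent bias, the component still held 38.6% of the within-group variance (36.8% to 43.9% with any slide left out), and after removal of the mean of each GC class it held 35.5% (34.6% to 41.4%). RNA quality and the state of the cultures stay open, and no biological explanation was tested, since the labels divide no group further.

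The calls at 1.22, 2.15 and 3.77 µg/L share the control arrays, and the counts fell to 11, 5 and 362 without control arrays 1 and 5. At 3.77 µg/L other pairs of control arrays were also left out, over the 19799 probes with no missing value. Pairs with only array 1 or only array 5 gave 321 to 633 calls, and pairs with neither gave 1659 to 4269. A similar fall thus came from leaving out either array together with another. If the control arrays deviated by chance and the exposed cultures did not, comparisons with the 0.69 µg/L arrays, which use no control array, should call few probes: they called 0 at 1.22 µg/L, 2 at 2.15 µg/L and 222 at 3.77 µg/L. For 215 of the 1568 calls at 3.77 µg/L, also made in the same direction against 0.69 µg/L, this argues against the control arrays as the source. For the rest the deviation of the control arrays and a response that is already under way at 0.69 µg/L cannot be told apart, because both lower the count against 0.69 µg/L. Against 0.69 µg/L the called probes kept 65.4%, 63.0% and 68.6% of their median change, a value that the selection of the probes on the same exposed arrays raises.

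In the submitters' table of log2 values, the columns named for replicates 1 and 2 at 1.22 µg/L followed their own scanner tables at rho = 0.918 and 0.923 across probes and each other's at 0.995 and 0.992. If the columns were exchanged, the scanner tables should deviate like the other arrays of their own slide, and they did: the mean r with the own slide exceeded that with the exchanged slide by 0.49 for replicate 1 and 0.70 for replicate 2. This is consistent with an exchange in the value table and not in the scanner tables. Both columns belong to one group, so counts of calls without the slide as a block do not depend on it.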

How the results depend on the processing

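The sets without control arrays 1 and 5 or without arrays 2 and 5 at 6.63 µg/L, and all alternatives for the shared calls except split controls, were chosen after seeing the data. All 192 values of the named contigs under the alternatives kept their direction and stayed past the threshold (with the filter on all 30 arrays, contig15173, contig08443, contig00289 and contig11436 were not tested), and 0 of the shared calls at 6.63 µg/L turned direction in the settings compared. These settings refit the same arrays or most of them, so a turn of a call that passes in both fits was unlikely from the start. Relative to the median of all probes, the log2 fold change of contig15173 ranged from 7.22 to 9.46 and that of contig00289 from -4.70 to -3.92 over 7 scalings. With an array or slide left out, calls against the control ranged from 0 to 0 at 0.69, 1 to 202 at 1.22, 0 to 369 at 2.15, 202 to 2050 at 3.77 and 3375 to 5666 at 6.63 µg/L. With a slide left out they ranged from 2 to 17 and 2925 to 6788 for the steps to 3.77 and 6.63 µg/L, from 5581 to 9073 for the trend, 3645 to 4945 for the linear trend and 150 to 593 for shared calls, and the median benchmark from 1.75 to 2.99 µg/L. With the array median as scale, calls were 27, 29, 389 and 3039 from 1.22 to 6.63 µg/L, 5 and 3708 for the steps, 5686 for the trend, 3174 for the linear trend and 217 shared. The replicate block (slide, fixed) gave 529, 723 and 3402 calls at 1.22, 2.15 and 3.77 µg/L, 72 for the step to 3.77 µg/L and 1589 shared, and as a random block 495, 735, 3446, 69 and 1492. It changed no other call by over 1.5-fold. Quantile normalization gave 208 calls at 1.22 µg/L, normexp 1026 at 3.77 µg/L, normexp with quantile normalization 217 at 1.22 µg/L, and no filter 83 at 1.22 µg/L, 852 at 3.77 µg/L and 449 shared. The step to 3.77 µg/L gave 25 calls with cyclic loess, normexp or the submitters' values, 34 with normexp and quantile normalization and 5 with the filter on all 30 arrays. Only the 10 arrays compared gave 46, 556 and 2570 at 2.15, 3.77 and 6.63 µg/L. The trend gave 3226 calls at an adjusted p under 0.001 and 2196 without 6.63 µg/L. Split controls gave 173.5 shared calls. The benchmark median was 5.08 µg/L with fewer curves and 5.515 µg/L at 2 residual SDs. Without control arrays 1 and 5 there were 11, 5 and 362 calls from 1.22 to 3.77 µg/L and 275 shared. Without arrays 2 and 5 at 6.63 µg/L there were 205 at 1.22, 269 at 2.15 µg/L and 23 for the step to 3.77 µg/L. The stricter adjusted p lowers the trend count by construction, and for the others the cause was not tested. Gene lists and 1 probe per gene name were not run, since probes carry no gene names. On the median array 50.9% of spots were well above background, and whether dim signals hid small changes was not tested.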

Other observations

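The patterns in this part were noticed in the data, and the tests were chosen before their own results were seen.

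Some transcripts passed from undetected to detected. At 6.63 µg/L 71 probes of 55 contigs that were well above background on 0 of 5 control arrays were so on all 5 exposed arrays, and both probes did this in 16 contigs, while 13 probes of 9 contigs went the other way. Probes of 14 contigs were gained at 3.77 µg/L, of 43 at 2.15 µg/L, of 106 at 1.22 µg/L and of 1 at 0.69 µg/L, with both probes gained in 3, 1, 5 and 0 contigs and 0, 0, 3 and 0 probes lost. The hypothesis that exposure switched transcripts on was set against the detection limit of the arrays. The gain exceeded the loss at every concentration, and more contigs were gained at 1.22 than at 6.63 µg/L. The control had the lowest number of probes detected on all 5 arrays (14908) and 1.22 µg/L the highest (19468). A detection limit that differs between groups may account for part of the gain, and the explanations cannot be told apart.

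Probes that rose at 6.63 µg/L were called at 3.77 µg/L more often than those that fell. Of the 2008 rising probes without a missing value, 20.3% were already called in the same direction at 3.77 µg/L, against 9.9% of the 3166 falling ones. The hypothesis was that rises begin at a lower concentration than falls. Matched on the size of the change at 6.63 µg/L, the shares were 19.7% and 10.1%, so matching changed them little on all arrays. The matched difference was 9.6 percentage points, but it ranged from 3.7 to 9.6 with any slide left out. On all arrays, larger changes among the rising probes thus accounted for little of the difference. The difference itself was not stable between slides, so the limit set beforehand for excluding the size of the changes was not met. After cyclic loess the matched difference was 2.0 percentage points (1.4 to 3.3), which suggests that scaling to the 75th percentile contributes to it. Whether rises begin earlier is left undecided. Among changes of at least 4-fold, for which the difference was not tested, 117 of 317 rises and 31 of 278 falls were called at 3.77 µg/L, and 121 of 389 and 40 of 221 after cyclic loess.

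Contigs on the array shared little probe sequence. Linking contigs whose probes share at least 40 nt merged the 1187 contigs with a probe higher at 6.63 µg/L into 1182 sequence groups and the 1976 with a lower probe into 1970. The largest group among the higher ones held 5 contigs.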
